A study of Arabidopsis thaliana with 12 samples.

How the data were processed

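RNA was measured on 12 one-colour Affymetrix arrays of Arabidopsis thaliana, 3 for each combination of 2 genotypes (wild type Col-0 and a chitin receptor mutant) and 2 treatments (chitooctaose at 1 uM, or water, for 30 minutes). Per the labels' protocols, whole seedlings were grown in liquid MS medium for 14 days in constant light at 23 °C, RNA was extracted with Trizol, and biotinylated cRNA was made from 8 ug of total RNA. The labels give the dose as "um", which is read here as micromolar. The deposited values are 1 intensity per probe set on a linear scale. How the authors summarised, background corrected and scaled these intensities is not given in the sources used here. The deposited intensity columns were neither quantile normalized nor scaled to 1 mean, as tested on the values, and their medians lay between 177.7 and 200.8.

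All 12 arrays were used. Values below 0 would have been set to 0, then log2(value + 16) was taken and no further scaling was applied. The 64 control probe sets were left out, which leaves 22746 tested. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a mean-variance trend, 8 residual and 8.3 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22746, two-sided, within each comparison. The 5 comparisons were chitooctaose against water in wild type and in the mutant, the difference of these responses, and mutant against wild type in water and in chitooctaose. Figures and annotation used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Groups, comparisons, tests, gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, apart from those said to be chosen later.

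The platform annotation names 1 gene for 13513 probe sets (13350 genes), several for 503 and none for 8730, which are unnamed here rather than without a gene. Of the 13513, 13436 matched the gene table of assembly TAIR10.1 and 77 kept the symbol of the annotation. That table served for names and for the order of neighbouring genes, and no coordinates are given since no genome build is named for the arrays. Because the annotation is partial, 58 of the 406 members of the 23 gene lists were measured. The lists cover WRKY factors, pattern receptors and partners, AP2/ERF factors, zinc finger and other stress regulators, MAP kinases, calcium, jasmonate, ethylene, salicylic acid, tryptophan and camalexin, phenylpropanoids, chitinases, E3 ligases, syntaxins, clock, photosynthesis, root, heat shock, low oxygen, abscisic acid and cold, auxin, wall remodelling and reference genes. No member was measured for 4 of them (MAP kinases, tryptophan and camalexin, phenylpropanoids, and syntaxins), which were not analysed here. The 7 lists with at least 3 measured members were tested with limma's camera, preset inter-gene correlation 0.01, adjusted over lists within a comparison. The highest mean probe set stood for a gene with several.

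Genes named in each comparison are the 14 largest increases and 8 largest decreases by log2 fold change among called probe sets of 1 gene whose 3 arrays of one group all lie above the 3 of the other (for the difference of responses, within wild type). Up to 4 members of each list with the largest called change, or the 2 with the lowest p where none is called, are named too. Separation of 3 against 3 arrays occurs by chance for 10% of probe sets, and a permutation test of 3 against 3 cannot give a two-sided p under 0.1.

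Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, leaving out the dimmest 40% of probe sets, the replicate number as a block, no mean-variance trend, only the groups of the comparison, a 2-fold minimum, leaving out each array in turn, and for lists an estimated correlation and fry. Wild type calls that also hold against the mutant water arrays were added after seeing the data. So were 43 further gene groups (families of at least 5 genes by symbol and chloroplast-encoded genes), chosen once the annotation was seen and before any test on them. The scripts were tested on simulated data. For the wild type comparison over 22746 probe sets 53.7% of changes of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold were recovered with 8 false calls, and for the difference of responses over 22746 probe sets 25.4%, 67.2% and 93.9% with 9. Of 200 simulated sets of 8 unchanged genes 3.5% had a camera p under 0.05. Array dates and batches were not used here, since none are given.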

Results

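The series holds 12 one-colour arrays of RNA from whole Arabidopsis thaliana seedlings, grown for 14 days in liquid medium and then given chitooctaose or water for 30 minutes. Chitooctaose is a soluble fragment of chitin, the polymer of fungal cell walls. The 2 genotypes were wild type Col-0 and a mutant of the chitin receptor, and each of the 4 combinations of genotype and treatment had 3 arrays titled as biological replicates. Each array gave 1 intensity per probe set, and the 22746 probe sets that are not controls were tested. Median intensities of the 12 arrays lay between 177.7 and 200.8. Arrays of 1 group correlated across probe sets with r from 0.984 to 0.993. The number of arrays limits the precision of every value below. Fold changes are differences of mean log2(intensity + 16), which makes those of dim genes smaller than the ratio of their intensities. Errors after ± are standard errors of the fit on 3 arrays per group, unless given as SD. No probe set is named for the receptor gene CERK1, so its transcript was not analysed here and the genotype labels were not checked by it.

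The first comparison asks which transcripts respond to chitooctaose in wild type. AT1G07160, a protein phosphatase 2C, rose by 5.59 ± 0.20 on the log2 scale (adjusted p = 9.8e-13), from a mean intensity of 23.1 ± 10.9 (SD, n = 3) in water to 1819 ± 92.9 (SD, n = 3) with chitooctaose. The transcription factor gene WRKY53 rose by 4.59 ± 0.12 and the zinc finger repressor gene STZ by 4.41 ± 0.09. CML37 and AT3G01830, both coding for calmodulin-like proteins, rose by 4.74 ± 0.18 and 4.71 ± 0.14. Increases of 4.86 ± 0.17 for AT1G24140, a matrix metalloproteinase, 4.83 ± 0.11 for AT1G66090, a TIR-NBS protein, and 4.79 ± 0.19 for AT3G12910, a NAC-domain protein, were of like size. The other 6 of the 14 largest increases, in AT3G02840, AT5G05300, AT2G32030, AT5G46295, AT5G52760 and AT1G05575, ranged from 4.18 to 4.69. Decreases were smaller. The 8 largest ran from -2.59 ± 0.11 for AT2G20670 to -1.86 ± 0.10 for WAG2, an AGC protein kinase gene, and took in AT1G04770, AT5G39520, AT5G03230, AT2G28200, AT4G35720 and AT3G07350.

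Among the gene lists, E3 ubiquitin ligases of elicitor responses moved most. PUB23 rose by 2.92 ± 0.09, PUB24 by 2.79 ± 0.10, PUB22 by 2.22 ± 0.10 and RING1 by 1.83 ± 0.10, while PUB19, the other of 5 measured, was not called. The list shifted upward (camera adjusted p = 2.5e-09, and 0.012 with an estimated correlation). In the list of calcium sensors, kinases and pumps all 8 measured genes code for calmodulin-like proteins, so it says nothing of kinases or pumps in any comparison. Of these 8 genes 6 rose, CML42 by 2.16 ± 0.12 and CML41 by 0.79 ± 0.16. The list shifted upward (adjusted p = 5.3e-07, and 0.028 with an estimated correlation). Of 7 WRKY genes 3 rose, WRKY53, WRKY22 (2.04 ± 0.10) and WRKY6 (0.97 ± 0.09), with adjusted p = 0.00035 for the list and adjusted p = 0.055 with an estimated correlation. Of 10 chitinase and chitinase-like genes 5 rose, AT4G01700 by 2.08 ± 0.10, AT1G02360 by 1.61 ± 0.09 and AT2G43620 by 1.52 ± 0.09 among them, and AT2G43600 fell by 0.59. The list gave adjusted p = 0.00035, and adjusted p = 0.055 with an estimated correlation. In 3 of the 6 fits that left out an array the call of AT2G43600 was lost, its adjusted p running from 0.012 to 0.11. BIK1, a receptor-like cytoplasmic kinase gene, rose by 1.27 ± 0.08, the 1 called of 4 pattern receptors and partners (list adjusted p = 0.014, and adjusted p = 0.064 with an estimated correlation). The others measured were AT5G18610, EFR and FER, so no chitin receptor gene was among the 4. In the auxin list IAA29 fell by 0.76 and GH3.3 fell by 0.60 of 3 measured (adjusted p = 0.014, and adjusted p = 0.055 with an estimated correlation). Adjusted over the list alone, the counts were 4 rose for E3 ligases, 6 for calcium, 3 rose and 1 fell for WRKY, 5 and 2 for chitinases, 2 rose for receptors and 2 fell for auxin. No photosynthesis gene of 3 was called by limma, with 0 at an unadjusted p under 0.05, and the list did not shift (adjusted p = 0.37).

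Lists with 1 or 2 measured members were described without a set test. The ERF gene AT1G33760 rose by 2.02 ± 0.19 and SAG101, a lipase-like partner of EDS1, by 1.11 ± 0.16, as did the cold-regulated COR15A by 0.92 ± 0.12. The defensin gene PDF1.2 fell by 0.70, AT3G10020 of the low oxygen list fell by 0.62 and EXPA8 of the wall list fell by 0.62. Both measured root and root hair markers, the expansin genes EXPA7 and EXPA18, fell by 0.57 and fell by 0.58. EIN3, GI, AT5G48570, ORA47, JMT, COR47, XTH16 and the reference gene AT4G34270 were not called. For these lists the count adjusted over the list alone was 1 more for the clock gene GI, 1 more for AT5G48570 and 1 more for COR47.

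In total 4298 probe sets changed in wild type (limma, 18.9% of those tested), 2007 higher and 2291 lower, and under quantile normalization 2224 were higher and 3551 lower. Changes of at least 2-fold were 624 higher and 130 lower, and those of at least 4-fold 236 higher and 8 lower. Replicate 1 of wild type with chitooctaose had the largest residual SD of the 12 arrays, 0.210 against 0.142 to 0.182 for the others, and leaving out single arrays gave from 3124 to 4393 calls. More were higher than lower without wild type chitooctaose replicate 1 (2259 and 1790), without wild type water replicate 1 (1883 and 1636) and without wild type water replicate 2 (1756 and 1368). Of the 4298, 2521 also differed in the same direction from the mutant water arrays, a comparison chosen after seeing the data, with 1432 higher and 1089 lower.

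**Figure D1:**
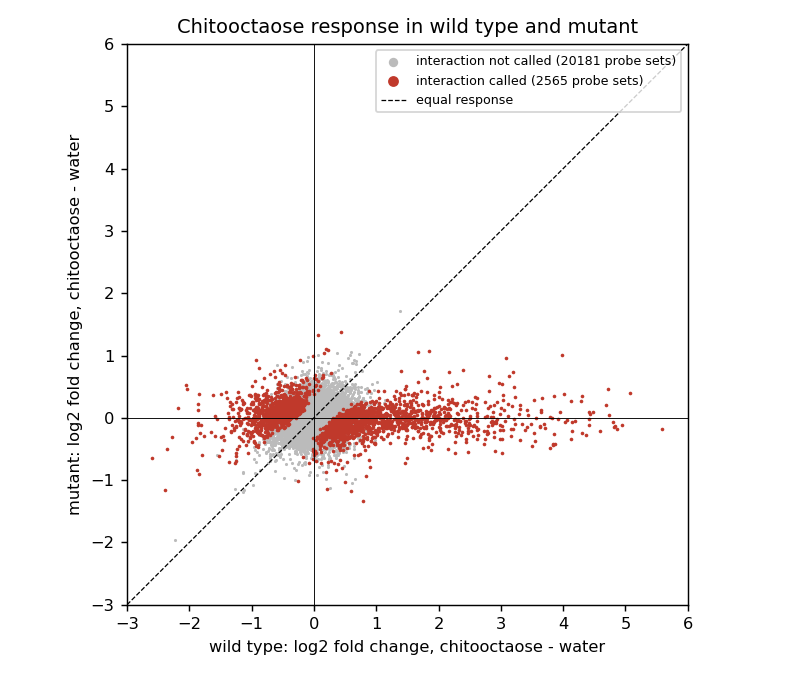
Log2 fold change with chitooctaose in the mutant (vertical axis) against that in wild type (horizontal axis), 1 point per probe set. The 624 probe sets raised at least 2-fold in wild type have a median change of -0.01 in the mutant.

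The second comparison asks the same of the receptor mutant. The changes were few, and most were small. AT2G04070, coding for a MATE efflux protein, rose by 1.10 ± 0.15 (adjusted p = 0.00057), from an intensity of 228 ± 9.62 to 507 ± 16.1 (SD, n = 3 each), and its relative AT2G04050 rose by 0.88 ± 0.13. The thionin gene AT1G66100 rose by 1.06 ± 0.14, AT1G26380, an FAD-linked oxidoreductase, by 1.00 ± 0.11 and PDF1.2 by 0.71 ± 0.11. AT1G26380 also rose in wild type, by 3.99 ± 0.11, whereas PDF1.2 fell there by 0.70, and both responses differed between the genotypes (adjusted p = 4.6e-10 and 6.7e-06). AT5G25240 was lower by -1.08 ± 0.10 and SIS by -0.91 ± 0.10, and AT3G21670, a nitrate transporter, by -0.73 ± 0.09. The rest of the 22 named genes were AT4G39675 (0.93), AT2G18190 (0.85), AT3G28580, AT3G29970, AT4G26460, AT5G10040, AT4G31020, AT3G60420 and AT1G57630 among increases and AT3G07350 (-0.84), AT4G33960, AT3G15720, AT4G33666 and AT2G47440 among decreases. Leaving out single arrays ended the calls of 6 of the 22, AT3G15720 and AT3G60420 in 6 of 6 fits, AT4G26460 in 4, AT1G57630 and AT3G28580 in 3 and AT4G33666 in 2.

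Of the 10 chitinase genes 4 rose in the mutant, CHI by 0.53 ± 0.12 and AT1G02360, AT2G43610 and AT2G43620 by 0.39 each, and adjusted over the list alone 4 rose and 1 fell. The list gave adjusted p = 0.00051, with adjusted p = 0.13 with an estimated correlation and 0.0911 by fry. Each of these 4 calls was lost in at least 5 of the 6 fits without an array. AT2G28200, a zinc finger gene, fell by 0.39, and lost its call in 5 of 6 such fits. The auxin list shifted upward (adjusted p = 0.032, with adjusted p = 0.13 with an estimated correlation and 0.113 by fry) with 0 of 3 members called by limma, 1 at an unadjusted p under 0.05 and 1 adjusted over the list alone. Limma called 0 of 7 WRKY genes, 0 of 8 calcium genes and 0 of 5 E3 ligase genes, where 1, 3 and 2 had an unadjusted p under 0.05. Adjusted over the list alone these counts were 0 for WRKY, 1 rose and 1 fell for calcium and 2 rose for E3 ligases. EXPA7 and EXPA18 had values of -0.05 ± 0.12 and -0.02 ± 0.11.

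In the mutant 339 probe sets changed (1.49%), 164 higher and 175 lower, and 2465 had an unadjusted p under 0.05. Only 13 higher and 7 lower reached 2-fold. Over all called probe sets the changes ran from -1.96 to 1.71, beyond those of the genes named above. The count was 189, 231 and 243 without mutant chitooctaose replicates 1, 2 and 3, and 167, 185 and 155 without mutant water replicates 1, 2 and 3. More were higher than lower without mutant chitooctaose replicate 3 (136 and 107) and without mutant water replicate 3 (87 and 68), while of these 6 fits the lower ones led by most without mutant chitooctaose replicate 2 (81 and 150). Quantile normalization gave 676 and median centring 672.

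The third comparison asks whether the response itself differs between genotypes, as the mutant response minus that of wild type. Genes are named here only if their wild type groups did not overlap, a rule that favours genes responding in wild type. Among genes so chosen, those that responded most in wild type had the most negative differences. AT1G07160 differed by -5.77 ± 0.28 (adjusted p = 1.5e-10), WRKY53 by -4.81 ± 0.17, CML37 by -4.69 ± 0.25 and STZ by -4.53 ± 0.13. In the mutant WRKY53 stood at 60.8 ± 10.6 in water and 49.7 ± 3.15 with chitooctaose, against 87.7 ± 10.7 and 2486 ± 209 in wild type (SD, n = 3 each). AT1G24140, AT1G66090, AT3G12910 and AT5G46295 complete the 8 largest negative differences, between -5.04 and -4.63. Under the same rule the 14 largest positive differences belonged to genes that fell in wild type. They were led by AT5G03230 (2.59 ± 0.16), which fell by 2.06 in wild type and rose by 0.53 in the mutant. AT4G02090 followed with 2.22 ± 0.24, and WAG2 (1.77 ± 0.14), the cyclin-dependent kinase inhibitor gene SIM (1.60 ± 0.20), the ERF gene AT5G61590 (1.61 ± 0.10) and ATL8 (1.54 ± 0.17) were among the 14. Each such difference is also the genotype difference in chitooctaose minus that in water, so a lower level in mutant water adds to it.

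The lists that rose in wild type had negative differences. All 4 E3 ligase genes that rose in wild type differed, PUB24 by -2.92 and PUB22 by -1.93 (4 lower of 5, list adjusted p = 3.5e-09, and 0.013 with an estimated correlation). So did 6 of 8 calcium genes, CML42 by -2.66 and CML41 by -1.16 (list adjusted p = 8.3e-08, and 0.02 with an estimated correlation). For WRKY genes 3 of 7 were lower (adjusted p = 0.00023, and adjusted p = 0.052 with an estimated correlation), and of the chitinases 4 were lower and 1 higher of 10 (adjusted p = 0.017, and adjusted p = 0.15 with an estimated correlation). In the auxin list GH3.3 (0.96) and IAA29 (0.76) were higher of 3 (adjusted p = 0.0021, and 0.034 with an estimated correlation). BIK1 differed by -1.41, and the receptor list had adjusted p = 0.06. Adjusted over the list alone, the numbers higher and lower were 0 and 4 for E3 ligases, 0 and 6 for calcium, 1 and 3 for WRKY, 2 and 4 for chitinases, 2 and 0 for auxin and 0 and 1 for receptors. The root markers EXPA7 (0.52) and EXPA18 (0.55) were higher here, and lost their calls in 9 and 6 of the 12 fits without an array.

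The difference was called for 2565 probe sets (11.3%), 1060 higher and 1505 lower, and under quantile normalization 2041 were higher and 1670 lower. Of the 624 probe sets raised at least 2-fold in wild type, 618 (99%) had a called difference, and their median change in the mutant was -0.01 (quartiles -0.12 and 0.14). In the mutant 27 of the 624 were called in the same direction and 14 in the opposite one. All 236 raised at least 4-fold had a called difference. Of the 130 lowered at least 2-fold, 120 (92.3%) had one, their median change in the mutant was -0.10, and 26 were called in the same direction there and 5 in the opposite one. The 624, 236 and 130 were chosen on the wild type response, which is itself part of the difference. That choice raises the shares with a called difference, so they are not separate support. The mutant changes come from other arrays. In water 70 of these 130 were called lower and 9 higher in the mutant than in wild type (median -0.38). For the 624 these counts were 97 and 85 (median -0.06). The comparison in water shares the wild type water arrays with the wild type response. Across all probe sets, which are not independent replicates, the responses of the genotypes correlated with r = 0.061 (jackknife SE 0.054) and rho = 0.036, and 53.1% (jackknife SE 5.35) of the wild type calls had the same sign in the mutant. Yet 76 probe sets were called higher in both genotypes and 92 lower in both, with odds ratios of 9.23 and 10.3, and 28 and 33 were called in opposite directions, with odds ratios of 1.98 and 2.27.

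**Figure D2:**
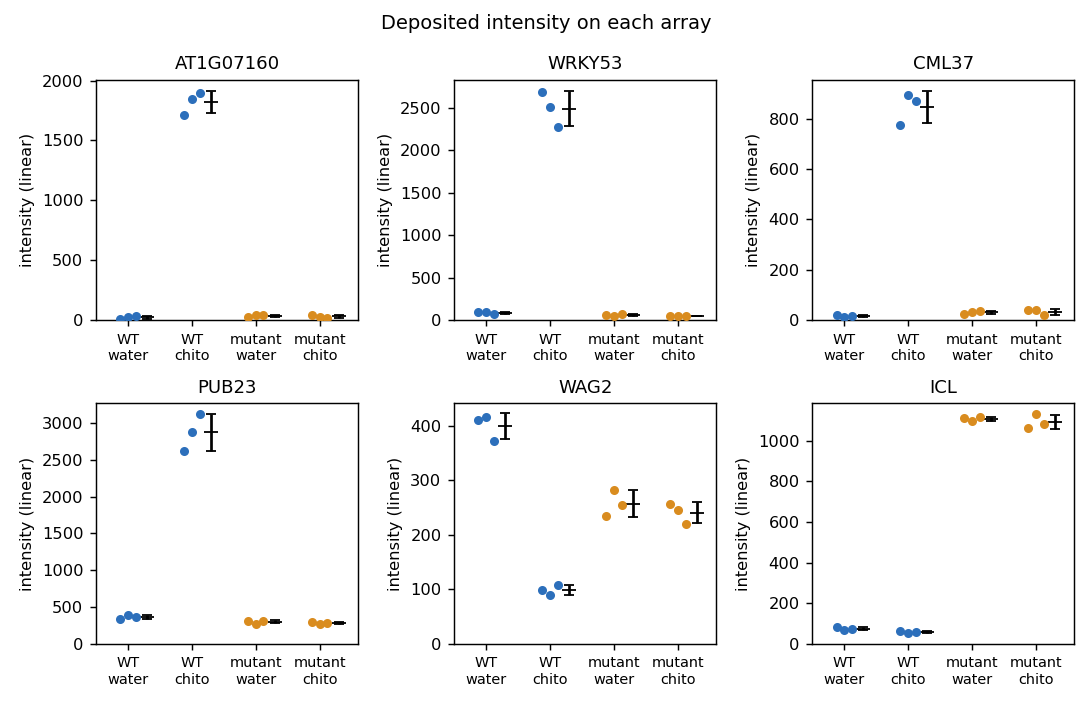
Deposited intensity (linear axis from 0) on each of the 12 arrays for 6 genes, with points for arrays and bars for the mean and SD of each group of 3. WRKY53 has a mean of 2486 in wild type with chitooctaose and of 87.7, 60.8 and 49.7 in the other groups, while ICL has 1109 and 1091 in the mutant groups and 74.4 and 58.2 in wild type.

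The fourth comparison, mutant against wild type in water, asks what the genotypes differ in without chitooctaose. ICL, isocitrate lyase of the glyoxylate cycle, was higher in the mutant by 3.64 ± 0.09 (adjusted p = 4.4e-14), at 1109 ± 10 against 74.4 ± 6.43 (SD, n = 3 each). DFR, an enzyme of anthocyanin synthesis, was higher by 3.08 ± 0.20, APL3, a subunit of ADP-glucose pyrophosphorylase, by 2.17 ± 0.16, and the sugar transporter gene SAG29 by 2.06 ± 0.15. AT1G80130 (3.02), AT4G17660 (2.70), AT2G04070 (2.54) and CML41 (2.29 ± 0.16) were also among the 14 largest increases of probe sets tied to 1 gene. The others were AT1G43910, AT1G76960, AT5G60250, AT1G78410, AT2G25510 and AT5G03350. Lower in the mutant were AT5G46295 (-1.64 ± 0.15), AT1G52070 (-1.51 ± 0.13), AT1G54050, AT1G52060, the auxin-conjugating enzyme gene WES1 (-1.42 ± 0.12), AT3G19430, GAT1_2.1 and the peroxidase gene AT1G49570 (-1.32 ± 0.10).

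The chitinase genes went both ways in water, with 3 of 10 higher, CHI, ChiC and AT2G43620, the last by 1.01, and 5 lower, AT1G02360 by -0.99 and AT2G43610 by -0.94 (list adjusted p = 0.45). AT1G56680, another of the 5, lost its call in 5 of 6 fits without an array. Of the calcium genes CML41 and AT3G47480 (0.98) were higher, and the list sat at the threshold (camera adjusted p = 0.0497, and adjusted p = 0.491 with an estimated correlation). The auxin list, with WES1 lower, had the same adjusted p = 0.0497 and adjusted p = 0.285 with an estimated correlation. Quantile normalization ended both calls, at camera adjusted p = 0.155 for calcium and 0.101 for auxin. The replicate number as a block ended them too, at camera adjusted p = 0.055 each. RING1 was higher by 1.23 and PUB22 lower by -0.56. Of the WRKY genes WRKY53 (-0.44) and WRKY6 (-0.33) were lower, calls lost in 4 and 5 of 6 fits without an array, as was that of BIK1 (0.27) in 5, of FER (-0.28) in 3 and of SAG101 (0.58) in 6. Adjusted over the list alone, the numbers higher and lower were 3 and 5 for chitinases, 3 and 1 for calcium, 0 and 2 for auxin, 1 and 2 for E3 ligases, 0 and 2 for WRKY and 1 and 1 for receptors. COR15A was higher by 0.91, and AT5G48570 (-0.89), AT3G10020 (-0.86) and EXPA8 (-0.47) were lower. The root markers EXPA7 (-0.65 ± 0.12) and EXPA18 (-0.62 ± 0.11) were lower, while 0 of 3 photosynthesis genes were called by limma and 0 had an unadjusted p under 0.05.

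In water 2351 probe sets differed (10.3%), 917 higher and 1434 lower in the mutant, and under median centring 1697 were higher and 1571 lower. At least 2-fold were 90 higher and 87 lower. Over all called probe sets the changes ran from -2.26 to 5.67, beyond those of the genes named above. This comparison and the wild type response share the 3 wild type water arrays. Of the calls, 660 were lower and 356 higher in both, where independent lists would share 144 and 80.9. Of the 660, 609 were not called for the mutant response and 496 were not called between genotypes in chitooctaose. Another 215 probe sets were higher with chitooctaose in wild type and lower in the mutant in water, where independent lists would share 127. The reverse held for 61, fewer than the 92.4 of such lists. In 20 simulations of unchanged groups that share these arrays there were 0 such calls, a value that the near absence of calls between unchanged groups fixes, so it says nothing of the overlap. The covariance of the fold changes was 0.0323, against 0.0129 to 0.0145 in 100 such simulations, a difference of 0.0186 from their mean. The correlation was 0.24 against a simulated mean of 0.50. The simulated noise was drawn independently for each probe set. The 3 shared arrays are too few to split, and part of the excess in the overlap may come from them.

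The last comparison sets the genotypes against each other after chitooctaose. The 8 genes lowest in the mutant relative to wild type had all risen with chitooctaose in wild type. AT5G46295 was lower by -6.27 ± 0.15, AT1G07160 by -5.35 ± 0.20, WRKY53 by -5.25 ± 0.12, STZ by -4.50 ± 0.09, with AT1G66090, AT5G05300, AT1G05575 and AR781 between -4.75 and -4.46. ICL was again higher, by 3.90 ± 0.09, as were AT2G04070 (3.44 ± 0.15), AT4G17660 (3.28 ± 0.25), AT1G80130 (2.24), DFR (1.83), AT2G04050 (1.87), AT5G03350 and AT5G60250. AT3G57160, AT1G19960, AT5G03230, AT1G17960, AT1G04770 and AT3G28540 make up the 14 largest increases of probe sets tied to 1 gene. The E3 ligase list was lower (4 of 5, PUB23 by -3.28, adjusted p = 1.8e-07, and 0.025 with an estimated correlation). RING1 of these 4 lost its call in 3 of 6 fits without an array. WRKY genes (1 higher and 3 lower of 7, adjusted p = 0.00037), calcium genes (2 higher and 4 lower of 8, adjusted p = 0.0013), chitinases (1 higher and 4 lower of 10, adjusted p = 0.0047) and receptors and partners (2 lower of 4, adjusted p = 0.027) shifted downward, with adjusted p = 0.107 for the first and adjusted p = 0.109 for the other 3 lists with an estimated correlation. In the last list BIK1 (-1.14) and FER (-0.38) were lower, while EFR (0.01) and AT5G18610 (0.07) were not called. ZAP1, the WRKY gene that was higher, lost its call in 5 of 6 fits without an array. The auxin list had 2 higher and 1 lower of 3 and did not shift (adjusted p = 0.31), and IAA29 of these lost its call in 4 of 6 such fits. Adjusted over the list alone, the numbers higher and lower were 0 and 4 for E3 ligases, 1 and 4 for WRKY, 2 and 4 for calcium, 1 and 4 for chitinases, 0 and 2 for receptors and 2 and 1 for auxin. EXPA7 (-0.13 ± 0.12) and EXPA18 (-0.07 ± 0.11) were not called.

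After chitooctaose 3929 probe sets differed between genotypes (17.3%), 1768 higher and 2161 lower in the mutant, and under quantile normalization 3576 were higher and 2129 lower. At least 2-fold were 157 higher and 671 lower. Over all called probe sets the largest increase was 5.29, above that of any gene named here. With the comparison in water, which shares no arrays with it, 331 calls were higher in both and 517 lower in both, where independent lists would share 71.3 and 136. Another 124 were higher in water and lower in chitooctaose, where such lists would share 87.1, and 94 were the reverse, against 111.

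**Figure D3:**
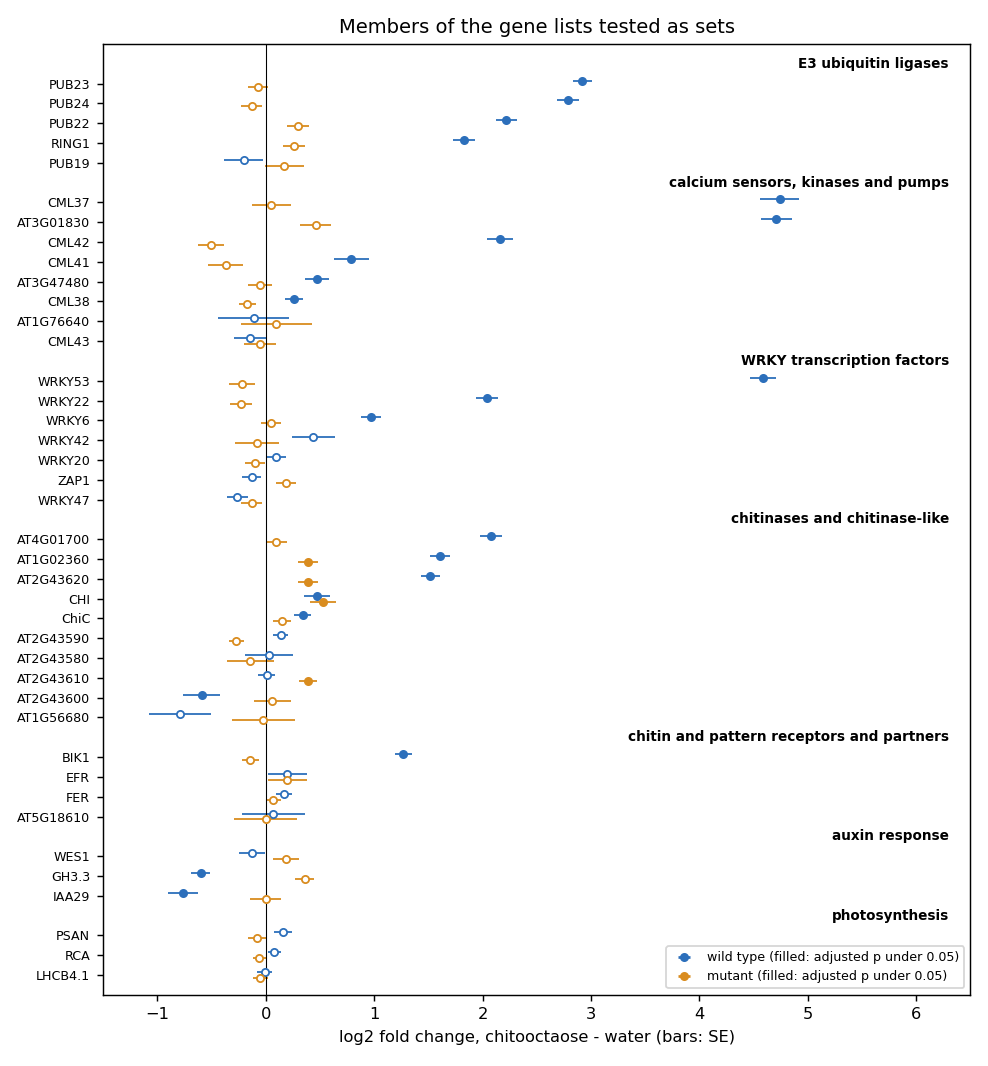
Log2 fold change with chitooctaose in wild type and in the mutant for members of the gene lists tested as sets, with bars for the standard error. PUB23 has 2.92 in wild type and -0.07 in the mutant, and CML37 has 4.74 and 0.05.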

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

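The simulation of shared water arrays and the test for a weaker wild type response were chosen only after the result was seen, and the root gene list was written after the values of EXPA7 and EXPA18 had been seen but before the rest of it was computed. The response to chitooctaose differed between the genotypes by the test of the difference itself for 2565 probe sets. Of 100 relabellings of treatment within genotype (of 200 possible), 2 gave as many, the real one included. Chance alone, with no effect of treatment in either genotype, is thus unlikely but not excluded. This relabelling breaks the wild type response too, so that the genotypes differ rests on the limma test and not on the relabelling. The highest other gave 2610, and it keeps the wild type groups and rearranges the mutant arrays, which points to a structure of the samples in which the wild type response sets the count. For the other comparisons the 10 splits of 3 against 3 are too few for a share under 0.05, and 1 of 10 splits, the real one, gave as many calls in each: the real and highest other counts were 4298 and 0 in wild type, 339 and 0 in the mutant, 2351 and 0 between genotypes in water, and 3929 and 0 in chitooctaose.

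Single genes with a tested difference of responses were, on the log2 scale, AT5G03230 (2.59), AT4G02090 (2.22), AT5G39520 (1.97), AT2G20670 (1.95), AT1G04770 (1.86), AT3G57160 (1.86), WAG2 (1.77), AT2G36090 (1.73), AT4G10910 (1.69), AT5G61590 (1.61), SIM (1.60), AT2G28200 (1.57), AT4G35720 (1.57) and ATL8 (1.54). Those with negative differences were AT1G07160 (-5.77), AT1G24140 (-5.04), AT1G66090 (-4.97), AT3G12910 (-4.86), WRKY53 (-4.81), CML37 (-4.69), AT5G46295 (-4.63) and STZ (-4.53). Among the lists the difference gave adjusted p = 0.00023 for WRKY genes, 8.3e-08 for calcium genes, 0.017 for chitinases, 3.5e-09 for E3 ligases and 0.0021 for auxin genes. With an estimated correlation these were adjusted p = 0.052, 0.02, 0.15, 0.013 and 0.034. Outside the genes tested, the control probe set for 25S rRNA was 2.63 times as high in the mutant with chitooctaose (3304 to 6009) as in the mutant with water (1092 to 2082), with exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give, whereas in wild type it was 1.48 times as high with water (2066 to 3407) as with chitooctaose (1000 to 2674).

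The wild type water arrays stood apart from the other 3 groups on the second principal component (15.1% of the variance), at -30.5 to -26.1, where the others lay between -1.06 and 18.9. The covariance between the wild type response and the genotype difference in water was 0.0323, above the highest of 100 simulations, 0.0145. This argues against noise of these shared arrays that is independent between probe sets. The simulations drew only such noise, so they cannot decide on noise that the arrays share across probe sets. A higher share of root RNA in the wild type water arrays may contribute. The median of 11 measured root-preferred genes of 39 listed was -0.58 with chitooctaose in wild type (bootstrap interval over genes -0.74 to -0.51). In mutant against wild type in water it was -0.67, and the 9 genes outside the fixed root list gave -0.61 and -0.83. The interval does not measure the spread between arrays. PYK10, 1 of the 11, at an intensity of 9846, had -0.05 ± 0.07 and -0.01 ± 0.07, so the 11 did not all move alike. The 9 measured of 31 nuclear photosynthesis genes, 3 of them also in the fixed list, had medians of 0.08 and 0.02. PRK (0.38) and SBPASE (0.44) were called higher in wild type and SBPASE (0.26) in water. That is the direction that a higher root share in the wild type water arrays would give. In chitooctaose, without those arrays, SBPASE was called lower in the mutant (-0.28, limma adjusted p = 0.0069) and PRK was not called (-0.26). Mean intensities were highest in wild type with chitooctaose (8220 for PRK and 6180 for SBPASE), which that share alone would not give. A response of root genes to the treatment and genotype stays among the open explanations, untested, and since the labels give no batch, batch and group cannot be told apart.

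The 339 calls in the mutant were weighed as a residual response. A weaker form of the whole wild type response is argued against by its increases alone. The 236 probe sets raised at least 4-fold in wild type had a median mutant change of -0.032 (bootstrap interval over probe sets -0.071 to 0.001). A weaker form of its decreases stays open. The 8 lowered at least 4-fold had a median of -0.40, and of the 130 lowered at least 2-fold 26 were called lower in the mutant and 5 higher. A difference between chitooctaose and water cultures that both genotypes share would give the calls the same sign in wild type. Of the 339 calls 237 had it (69.9%, exact interval over probe sets 64.7% to 74.7%), between the bounds of 60% and 80% set for it. Probe sets are not independent replicates, so neither interval measures the spread between arrays. This explanation and a genotype-specific one cannot be told apart. Of the 339, 168 were called in the same direction in wild type, 61 in the opposite one and 110 not at all, 179 had a called difference of responses, and 113 went the same direction as wild type without one. The mutant response and the genotype difference in water share the mutant water arrays. Of the 164 mutant increases 89 were called lower in the mutant in water, and of the 175 decreases 49 were called higher. Independent lists would share 10.3 and 7.06. In the same direction 41 were higher in both and 31 lower in both, against 6.61 and 11. The part that the shared arrays play was not tested. A response through other receptors was not tested.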

How the results depend on the processing

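The alternative that sets wild type chitooctaose against the mutant water arrays was chosen only after the result was seen, and the other alternatives here were planned. Of the named genes, 264 pairs of gene and comparison were refitted under the alternatives, which gave 3908 refitted values over all pairs. The 211 called pairs never changed direction, 182 of them kept the call in every alternative run and 29 lost it in at least 1 (161 losses). The 53 pairs not called gained a call 28 times, and 18 of them changed sign at least once (40 times), all with values near 0. The cause was not tested for any change below, except that a 2-fold minimum shrinks a count by construction. With a 2-fold minimum the calls were 754 in wild type, 20 in the mutant, 810 for the difference of responses, 177 between genotypes in water and 828 in chitooctaose. Wild type calls that also hold against the mutant water arrays were 2521. The mutant count of 339 became 676 with quantile normalization, 672 with median centring and 193 without a mean-variance trend, and leaving out single arrays gave 155 to 243. Leaving out single arrays gave 3124 to 4393 in wild type, 2029 to 3215 for the difference, 1583 to 1932 in water and 3181 to 4363 in chitooctaose, and for the correlation of the responses r from 0.021 to 0.088.

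Whether replicate numbers pair the arrays stayed unclear. Only 6 of 18 same-numbered pairs had residuals correlated over 0.1 (range -0.13 to 0.22), but 8 of 12 arrays correlated best with their own number. With the replicate number as a block the counts were 4488, 324, 2652, 2457 and 4062 in the order above, and the list shifts of calcium and auxin genes in water moved to adjusted p = 0.0554 each, the only calls of the fixed lists that the block changed, while among the gene families GLR in wild type went from 0.055 to 0.045 and PRA in water from 0.058 to 0.048, and 2 calls of named genes in the mutant were lost. Quantile normalization gave these lists 0.155 and 0.101. With an estimated correlation the list p values past the threshold became 0.0553 (WRKY), 0.064 (receptors), 0.0553 (chitinases) and 0.0553 (auxin) in wild type, 0.129 (chitinases) and 0.129 (auxin) in the mutant, 0.0523 (WRKY) and 0.15 (chitinases) for the difference, 0.491 (calcium) and 0.285 (auxin) in water, and 0.107 (WRKY), 0.109 (receptors), 0.109 (calcium) and 0.109 (chitinases) in chitooctaose. Fry gave 0.0911 for chitinases and 0.113 for auxin in the mutant, 0.000909 for receptors in the difference and 0.0037 for auxin in chitooctaose, and for E3 ligases in water it gave the opposite direction with adjusted p = 0.973.

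Sign changes of genes that were not called were these log2 values. With quantile normalization EIN3 had -0.013 in wild type, 0.022 in the mutant and 0.035 for the difference, RCA -0.006 in water, and in the mutant COR15A 0.014, EXPA18 0.009, GI 0.031 and XTH16 0.036. Median centring gave the last 4 values of 0.016, 0.001, 0.020 and 0.025. Without single arrays the ranges in the mutant were -0.009 to 0.335 for EFR, -0.274 to 0.004 for AT1G33760, -0.210 to 0.025 for ORA47, -0.051 to 0.001 for EIN3, -0.129 to 0.023 for SAG101, -0.060 to 0.084 for GI, -0.108 to 0.052 for EXPA18, -0.082 to 0.074 for COR15A and -0.039 to 0.023 for XTH16. In water they were -0.057 to 0.242 for AT1G33760, -0.093 to 0.148 for ORA47, -0.061 to 0.085 for GI, -0.010 to 0.117 for PSAN and -0.004 to 0.021 for RCA. EIN3 ran from -0.034 to 0.154 in wild type and from -0.182 to 0.006 for the difference, and in chitooctaose EXPA18 ran from -0.192 to 0.021 and AT4G34270 from -0.039 to 0.123. Alternatives for the receptor transcript were not run, as no probe set is named for it. Signal over background limits dim genes, whose fold changes the added 16 makes smaller.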

Other observations

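The test of windows along the genome was chosen only after the result was seen, and the gene families were chosen once the annotation was seen and before any test on them. Of 43 such groups the calmodulin-like CML genes rose in wild type (5 of 7, camera adjusted p = 2.1e-05, and adjusted p = 0.4 with an estimated correlation), as did U-box PUB ligases (5 of 9, adjusted p = 2.5e-05, and adjusted p = 0.35 with an estimated correlation). CML37, CML38, CML41, CML42 and CML43 are also in the calcium list, and PUB19, PUB22, PUB23 and PUB24 in the E3 ligase list. The CML and PUB groups thus repeat those lists in part, in every comparison below. Expansin EXPA genes fell (6 of 10, adjusted p = 0.013, and adjusted p = 0.4 with an estimated correlation), EXPA7 and EXPA18 among them, in arrays where 10 of 11 measured root-preferred genes were also lower (median -0.58). In water 13 of 69 chloroplast-encoded transcripts were higher in the mutant and 56 were not called (adjusted p = 8.9e-10, with adjusted p = 0.69 with an estimated correlation and 0.1 by fry), as were 3 of 5 CRR genes (adjusted p = 0.0016, and adjusted p = 0.3 with an estimated correlation). Of the XTH wall enzyme genes 4 of 9 were lower there (adjusted p = 0.0063, and adjusted p = 0.69 with an estimated correlation), as were 10 of the 11 root-preferred genes (median -0.67). Between the genotypes in chitooctaose 1 of 69 chloroplast-encoded transcripts and 1 of 5 CRR genes were higher, with adjusted p = 0.85 for each group. The mutant response gave chloroplast-encoded genes adjusted p = 5.8e-06 downward with 0 of 69 called by limma, 12 at an unadjusted p under 0.05, and adjusted p = 1 with an estimated correlation and 0.77 by fry, and CRR genes adjusted p = 0.0033 with 0 of 5 called, 4 at an unadjusted p under 0.05, and adjusted p = 0.38 with an estimated correlation. For the difference of responses 5 of 7 CML genes (adjusted p = 2.6e-06, and adjusted p = 0.4 with an estimated correlation), 4 of 9 PUB genes (adjusted p = 3.7e-05, and adjusted p = 0.38 with an estimated correlation) and 3 of 69 chloroplast-encoded genes (adjusted p = 0.0004, with adjusted p = 0.84 with an estimated correlation and 0.24 by fry) were lower. In chitooctaose 4 of 9 PUB genes were lower in the mutant (adjusted p = 3.7e-05, and adjusted p = 0.33 with an estimated correlation), 4 of 7 CML genes were lower and 1 higher (adjusted p = 0.00032, and adjusted p = 0.57 with an estimated correlation), and 3 of 6 NRPB genes were higher (adjusted p = 0.039, and adjusted p = 0.57 with an estimated correlation).

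Both treatments had 70 probe sets that differed at least 2-fold the same way between genotypes, 60 higher and 10 lower in the mutant. Of the 13217 genes that could be placed in gene order by TAIR10.1, 33 differed so, and the 70 were not all placed. Near the receptor gene lie 2 of the 33, ICL at 9 protein-coding places (3.64 in water and 3.90 in chitooctaose) and AT3G21620 at 1 place (1.71 and 1.70), the latter chosen after its values were seen. Of 12943 windows of 40 measured genes elsewhere 101 (0.78%) held as many, but this count was prompted by the same 2 genes, so it does not decide whether effects scattered over the genome would place them there. A wide block of DNA from another accession could raise the share of differing genes farther out, and 5 of 160 measured genes 21 to 100 places away (3.12%, upper 95% bound 7.14%) differed the same way in both treatments against 3% in the rest of the genome (Fisher's exact p = 0.82, two-sided), too few to decide it. Of the 40 measured genes nearest the receptor gene 5 did (12.5%), AT3G21670, UGT71B1 and AT3G22060 besides the 2 that prompted the count, all named after their values were seen. An effect of the mutation on its near neighbours stays open, untested.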
